A study of Mus musculus with 2 samples.

How the data were processed

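A pool of 18 hashed mouse melanoma tumors was profiled with the 10x Genomics 3' gene expression assay, with a parallel library for the hashtag antibodies. Per the labels' protocols, tumors were minced and digested with an enzyme, cells were stained with hashtag antibodies, equal numbers of cells per sample were combined, and CFP-positive tumor cells were sorted from the pool before loading. The deposited matrix holds raw UMI counts per gene and per hashtag in each barcode, and it was not normalized. Per the file headers the counts come from Cell Ranger 6.1.2, whereas the submitters' processing notes list Cell Ranger 2.1.1 with the GRCm38 build, and the sources used here do not resolve which applies. The filters behind the deposited barcode list are not given in the sources used here. Gene names are those of the deposited feature list. Coordinates were taken by gene ID from GENCODE M21, which is on GRCm38.

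Cells were kept with at least 1000 gene UMIs, at least 500 genes with a UMI and at most 15% mitochondrial UMIs. Hashtag counts of these cells were log-ratio transformed (CLR) and grouped by k-means with 1 cluster more than the 10 tags. For each tag, a negative binomial was fitted to the cluster with the lowest mean, after its top 0.5% of values was removed, and the 0.99 quantile was the cutoff. Tags came in pairs, which the plan allowed for as a tag combination. A cell with exactly 2 tags above their cutoffs, in a pair seen in at least 10 cells, was assigned to that pair. Barcodes with 3 or more tags were treated as doublets and left out, and cells with fewer than 2 tags were kept but unassigned. Doublets within 1 tumor are not seen by this rule. Barcodes under 800 UMIs served as a measure of RNA outside cells. In simulated tag counts of 18 pairs, 85.8% of single cells were assigned, 99.5% of them to the right pair, and 3.66% of mixed droplets were assigned to 1 pair. The simulated pairs had equal expected sizes, all tags had the same mean signal, and no cell was untagged. These shares may therefore not hold for small pairs or weak tags in the data.

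Counts were normalized to 10000 UMIs per cell and log-transformed for clustering, which used 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 (scanpy 1.11.5, igraph 0.11.9). Leading genes were ranked by fold over the other cells, with 5 CPM added to both and a UMI in at least 25% of the cluster's cells. A cluster was to be named from fixed markers of 12 cell types. No cluster had such a marker among its top 10 genes, so none was named. Levels were summed UMIs in CPM, scaled by the total of gene UMIs, with exact Poisson intervals, and shares have exact Clopper-Pearson binomial intervals, both at 95%. A count of 0 was read as allowing up to 3 counts.

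For 17 program lists, each cell's score was the mean of its log-normalized values over list members, with genes shared by 2 lists left out. Of the fixed members, 4 were not matched to the feature list. For all correlations, each cell was thinned without replacement to 26600 UMIs, the first quartile of kept cells rounded down. This left 1233 cells, of which 84 were in no tag pair, and left out 410. Pearson's r with the interferon-gamma score was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. The draws left out the members of all 17 program lists and were made gene by gene. Random lists therefore lacked the listed interferon, MHC and chemokine genes and the shared variation of a program. Pearson's r was recomputed after each tag pair's mean was subtracted and within each tag pair of at least 20 thinned cells. Genes with a UMI in at least 5% of kept cells were correlated with the same score, without the gene itself. Cells and genes are not independent replicates, so no p-value was computed. Genes were called by a size of 0.3 in r. In simulated counts of 10989 genes, with linked genes moved both ways, this size found 62.0% of genes with a log2 change of 1 per SD of the shared factor and 27.3% of genes with 0.5, and 0% of unlinked genes. For linked genes of at least 50 CPM the shares found were 100% and 96.3%. Unlinked genes had no variation of their own beyond counting noise in this simulation. The 0% therefore does not measure false calls in the data. A simulated list moved by the tumor alone had r of 0.552 pooled and -0.0616 within tumors, and -0.183 within tumors when all linked genes rose, since a rise in some genes lowers the share of the others.

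The filters, the gene lists, the marker lists, the minimum of 100 cells per tag pair and the rule for genes named in the text were set before the data were examined. The limit of 800 UMIs for free RNA, the minimums of 10 cells per pair and 20 thinned cells, the removal of the top 0.5% of background tag values and the ranking of leading genes were set later. Named genes are the 20 highest and 10 lowest in r with the interferon-gamma score outside its list, without genes whose symbols start with Rpl, Rps or mt (mitochondrial genome). Added to these are the 2 members of each program list with the highest CPM and the 1 with the largest absolute r, and the 3 leading genes of each cluster. Not every gene that this rule takes is reported here. Genes of cell type lists, Tyr, Tyrp1 and others in the closing section were chosen after their values were seen. The plan gave correlations within tags as a mean and SD. Medians and ranges are given instead, because the tumors belong to no stated group.

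The 3 comparisons between conditions and their tests were planned only if tags could be tied to conditions, and they were left out. Alternatives covered the UMI, mitochondrial and doublet filters, the clustering resolution and genes, thinning, a linear score, Spearman's rho, and a tag rule that needed the second tag at least 1 CLR unit above the third. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.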

Results

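Single-cell gene expression was measured in 1 pool of 18 mouse tumors grown from NMM, an NRAS-mutated mouse melanoma line, in Rag-deficient mice, which lack their own T and B cells. Cells of each tumor had been stained with hashtag antibodies, which carry a DNA tag that is read along with the RNA, and the pool was sorted for CFP-positive tumor cells, described in the labels as bystander cells. The labels list 3 conditions of 6 tumors each, named Ag-GAS + T, Mix PBS and Mix + T, and the design text states that tumors were exposed to T cells or to PBS as the control. One gene expression library and 1 hashtag library were made, so the data form 1 sample without replicates. The matrix held 32285 genes and 10 hashtags in 20917 barcodes, with 93843218 gene UMIs (unique molecular identifiers, each standing for 1 captured transcript).

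The design implies 3 comparisons, between Mix + T and Mix PBS, between Mix + T and Ag-GAS + T, and between Ag-GAS + T and Mix PBS. Neither the labels nor the hashtag names tie a hashtag to a condition, and conditions were not inferred from expression. These 3 comparisons were therefore not made. The values below describe the pooled cells and, where hashtags separated them, tumors of unstated condition. Intervals on counts and shares cover counting error only.

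Most barcodes held little RNA. Of the 20917 barcodes, 18473 (88.3%, exact 95% binomial interval 87.9 to 88.7%) had fewer than 800 gene UMIs, with a median of 569, and they held 11.4% of all gene UMIs. Cells kept for analysis numbered 1643 (7.85% of barcodes, interval 7.49 to 8.23%), with a median of 40785 UMIs and 5835 genes per cell and 73.1% of all gene UMIs. A further 437 barcodes passed the UMI and gene minimums but had more than 15% mitochondrial UMIs, and 199 carried 3 or more hashtags. Both sets were left out.

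**Figure D1:**
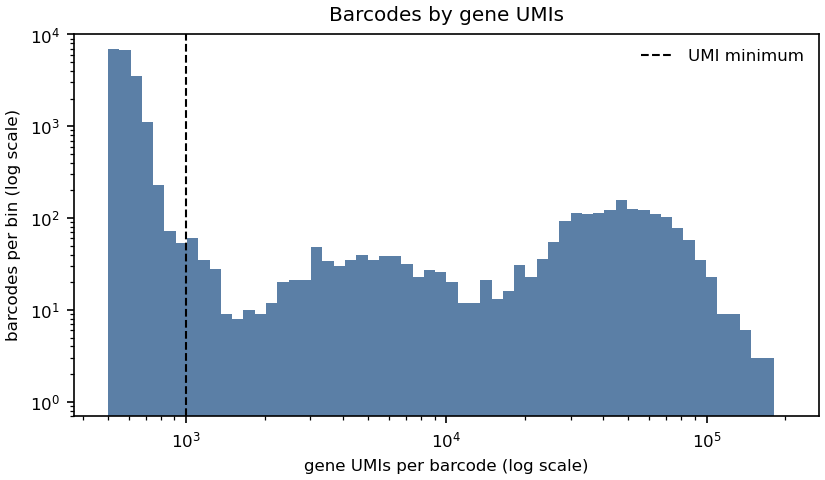
Number of barcodes (log scale) by gene UMIs per barcode (log scale) in the pooled library, with the minimum of 1000 UMIs as a dashed line. The 18473 barcodes under 800 UMIs form the tall peak at the left, and the kept cells, with a median of 40785 UMIs, form most of the peak at the right.

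Hashtags occurred in pairs. Of the 1643 kept cells, 1401 carried exactly 2 hashtags in 1 of 18 combinations, out of 45 possible pairs of the 10 tags. One more cell carried another pair, and 241 cells had fewer than 2 tags above background. In assigned cells the second most abundant tag had a median of 38.5 times the UMIs of the third, and the first had 1.27 times those of the second. The 18 tag pairs equal the number of pooled tumors, and each pair was taken as 1 tumor. That reading is an inference from the tags and is not stated in the labels. The tag pairs held 19 to 209 cells (median 75), and 6 of them held at least 100, the planned minimum.

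**Figure D2:**
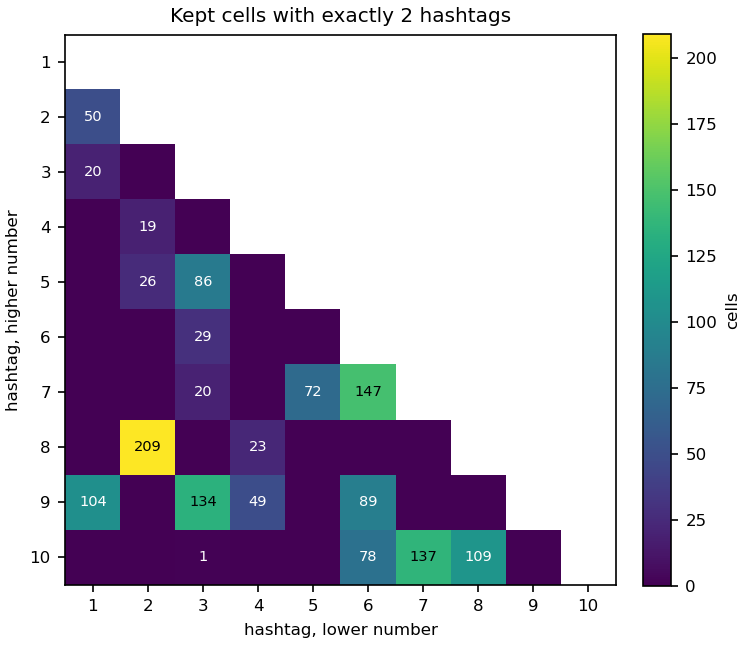
Kept cells with exactly 2 hashtags, by the lower-numbered hashtag (horizontal axis) and the higher-numbered one (vertical axis), with the number of cells written in each occupied square and shown by colour. The 18 used pairs hold 19 to 209 cells, and 1 cell carried a pair outside them.

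The kept cells fell into 5 clusters, none of which had a fixed cell type marker among its top 10 genes. Cluster 1 (558 cells, 34.0%, interval 31.7 to 36.3%) was led by Hist1h1b, a linker histone made in S phase, Cenpf, a kinetochore protein, and Prc1, a protein of the mitotic spindle. Cluster 2 (446 cells, 27.1%, interval 25.0 to 29.4%) was led by Cd74, the class II MHC invariant chain, AW112010 and Apod. Cluster 3 (358 cells, 21.8%, interval 19.8 to 23.9%) was led by Mgp, an inhibitor of calcification, Prg4, a lubricating proteoglycan, and Itga1, a collagen-binding integrin. Cluster 5 (104 cells, 6.33%, interval 5.20 to 7.62%) was led by Ung, a uracil glycosylase of DNA repair, Ctla2a and Nrarp. Cluster 4 (177 cells, 10.8%, interval 9.31 to 12.4%) was led by AY036118, Ccl5 and Gm42418. It had a median of 1216 UMIs per cell, and 140 of its cells lay outside the tag pairs. Its median mitochondrial share was 0.330%, against 2.45 to 3.04% in the other clusters and 0.197% in barcodes under 800 UMIs. Gm42418 stood at 8919 CPM in cluster 4, 2312 CPM over kept cells and 31584 CPM in barcodes under 800 UMIs. AY036118 stood at 1316, 256 and 4355 CPM in the same order. Cluster 4 may therefore hold barcodes without a full cell. The interferon-gamma response list stood at 6577 CPM, a unit scaled by the total of gene UMIs, in cluster 2, 3229 CPM in cluster 1, 1865 CPM in cluster 3, 3363 CPM in cluster 4 and 1453 CPM in cluster 5. Fibroblast genes stood at 1609 CPM in cluster 3 and 1417 CPM in cluster 2, against 419 CPM in cluster 1, 827 CPM in cluster 4 and 414 CPM in cluster 5. Of the 7 fibroblast markers, 5 had a UMI in at least 10% of the cells of cluster 3, 4 in clusters 2 and 5 and 3 in cluster 1, while 3 of the 10 melanoma markers did in each of these clusters. The tag pairs differed in their make-up. Cluster 2 held 0 to 56.7% of the cells of a tag pair and cluster 3 held 3.35 to 73.9%, and in the 6 tag pairs with at least 100 cells these shares were 37.4 to 56.7% and 3.35 to 15%. The clustering used interferon-induced genes, so these shares are not independent of the interferon lists.

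Transcripts of immune cells were scarce in the kept cells. The T cell list reached 1.22 CPM (exact 95% Poisson interval 0.977 to 1.52), the NK cell list 0.583 CPM, the B cell list 0.146 CPM and the dendritic cell list 1.66 CPM. The macrophage list stood at 6.37 CPM and the neutrophil list at 2.80 CPM, against 9.24 and 3.55 CPM in the barcodes under 800 UMIs. Erythroid genes reached 0.656 CPM, pericyte and smooth muscle genes 1.33 CPM, keratinocyte genes 8.21 CPM and endothelial genes 46.5 CPM. The last 2 lists rested on few genes. In cluster 1, Cdh5 and Egfl7 gave 45.4 and 10.2 of the 55.9 CPM of the endothelial list. Krt10 gave 8.74 of the 8.95 CPM of the keratinocyte list there. The fibroblast list reached 876 CPM, of which the collagen gene Col3a1 gave 749 CPM. The melanoma marker list reached 74.9 CPM, and no cluster was named from these lists. The pigment genes Tyr and Tyrp1, which encode enzymes of melanin synthesis, had no UMI in any of the 1643 cells, which allows a share of up to 0.183% of cells with a UMI, while Pax3, a transcription factor of the melanocyte lineage, reached 32.3 CPM. Mitf stood at 4.18 CPM, Pmel at 0.204 CPM, Sox10 and Dct at 0.0437 CPM each and Mlana at 0.0146 CPM. Only 3 of the 18 genes of the melanocytic list had a UMI in at least 5% of cells. The highest member of the melanocytic list (86.8 CPM) was Slc24a5, a melanosomal cation exchanger, at 48.6 CPM.

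Interferon-induced transcripts were abundant in the pool. The interferon-gamma response list (22 genes) reached 3654 CPM (interval 3639 to 3668), led by the GTPase gene Iigp1 at 731 CPM. The type I interferon list reached 9383 CPM, with Bst2, which tethers budding virions, at 3791 CPM and the ubiquitin-like modifier Isg15 at 1953 CPM. The class I MHC list reached 9695 CPM, with B2m, the class I light chain, at 2597 CPM and H2-D1 at 1767 CPM. The class II MHC list reached 145 CPM (interval 142 to 148), with Cd74 at 76.4 CPM and H2-Eb1 at 20.1 CPM. Chemokine genes reached 2822 CPM, mostly Cxcl10 (1374 CPM), a ligand of the chemokine receptor Cxcr3, and Ccl2 (842 CPM), which attracts monocytes. The barcodes under 800 UMIs gave 3741 CPM for the interferon-gamma list, 9832 CPM for the type I list, 11447 CPM for class I, 111 CPM for class II and 3645 CPM for chemokines, so the RNA in barcodes without a full cell held these transcripts too.

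Among the remaining lists, the TNF and NF-kB list reached 568 CPM, with Sod2, a mitochondrial superoxide dismutase, at 114 CPM and Tnfaip2 at 70.9 CPM. Immune ligands reached 515 CPM, of which Cd47, an inhibitor of phagocytosis, gave 365 CPM and Lgals9 92.8 CPM. Genes of cytokine signalling reached 594 CPM, with the kinase gene Jak1 at 93.6 CPM and the receptor gene Ifnar2 at 83.0 CPM. The neural crest and dedifferentiated list reached 1571 CPM, with fibronectin (Fn1) at 551 CPM and Tcf4 at 309 CPM. S phase genes reached 1803 CPM, with Nasp at 134 CPM and Pcna at 126 CPM, and G2/M genes 4966 CPM, with Hmgb2 at 562 CPM and Tubb4b at 360 CPM. The hypoxia and glycolysis list reached 5587 CPM, with Mif at 1155 CPM and Pgk1 at 1046 CPM, and the unfolded protein response list 1732 CPM, with the chaperone gene Hspa5 at 904 CPM and Pdia4 at 209 CPM. Immediate early and dissociation genes reached 1592 CPM, with Ier3 at 374 CPM and Jun at 266 CPM, p53 and cell death genes 720 CPM, with Bax at 246 CPM and Casp8 at 78.9 CPM, and genes of MAPK output 1514 CPM, with Ccnd1 at 584 CPM and Phlda1 at 238 CPM.

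In the 6 tag pairs with at least 100 cells, the interferon-gamma list ranged from 4615 to 6346 CPM (median 5629). Their class I list ranged from 12552 to 14575 CPM (median 13994), their type I list from 9755 to 12998 CPM (median 11898), their chemokine list from 3384 to 5307 CPM (median 4587) and their class II list from 121 to 387 CPM (median 273). The cell minimum bore on these ranges. With all 18 tag pairs, an alternative chosen after seeing the data, the interferon-gamma list ranged from 912 to 6346 CPM (median 1699), class I from 4116 to 14575 CPM (median 5443), type I from 4479 to 12998 CPM (median 7784), chemokines from 638 to 5307 CPM (median 1617) and class II from 0 to 387 CPM (median 5.55). Over the same 18, the ratio of the highest to the lowest level was 8.32 for chemokines, 6.96 for the interferon-gamma list, 3.54 for class I and 2.90 for type I. It was 2.30 for immediate early genes, 2.20 for p53 and cell death genes and 2.07 for hypoxia and glycolysis genes. The lowest ratios of the program lists were 1.36 for the unfolded protein response list and 1.32 for the MAPK list. Among single genes, Psmb9 ranged from 44.5 to 550 CPM, Igtp from 42.7 to 492 CPM, Cxcl10 from 329 to 2896 CPM and B2m from 1496 to 3515 CPM. Median UMIs per cell ranged from 31918 to 51546. As the tumors belong to no stated group, no test was run between them.

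**Figure D3:**
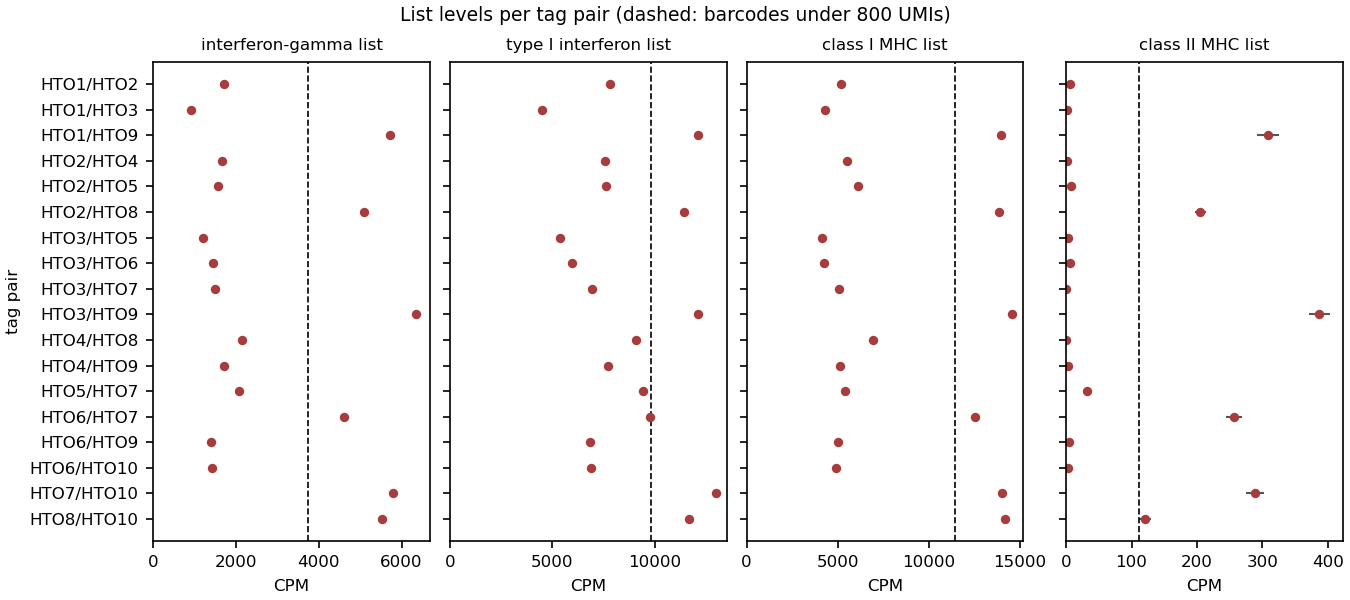
Levels (CPM, horizontal axes) of 4 gene lists in each of the 18 tag pairs (vertical axis), as points with exact 95% Poisson intervals, which are mostly narrower than the points. Dashed lines mark the level in barcodes under 800 UMIs, which is 3741 CPM for the interferon-gamma list, and the tag pairs range from 912 to 6346 CPM for that list.

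Cells with more of the interferon-gamma response also had more antigen presentation, type I interferon and chemokine transcripts. Across 1233 cells thinned to 26600 UMIs each, the interferon-gamma score had a Pearson r of 0.860 with the class I list, 0.799 with the type I list, 0.712 with chemokines and 0.70 with immune ligands. Each of these lay at or above the 99.96 percentile of 10000 random lists of matched size and expression. Those lists held no member of the program lists and were drawn gene by gene. High percentiles were therefore easy to reach for interferon-induced genes that vary together. After each tag pair's mean was subtracted, r was 0.707 for class I, 0.760 for type I, 0.576 for chemokines and 0.604 for immune ligands, and each was positive in 15 of the 15 tag pairs with at least 20 thinned cells. Cytokine signalling genes followed with r of 0.493 pooled and 0.489 within tag pairs, positive in 15 of 15. In the 6 tag pairs with at least 100 cells, r within the pair ranged from 0.495 to 0.772 (median 0.681) for class I and from 0.516 to 0.835 (median 0.674) for type I. Over all 15 the ranges were 0.495 to 0.833 (median 0.699) for class I and 0.516 to 0.943 (median 0.856) for type I. Among these 15, r of the type I list was at least 0.854 in every tag pair with fewer than 100 cells.

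Other lists had lower r with the interferon-gamma score. The TNF and NF-kB list had r of 0.364 pooled and 0.312 within tag pairs, positive in 13 of 15, and the class II list had 0.349 and 0.218. In the 6 tag pairs with at least 100 cells, r of the class II list was positive in 5 and ranged from -0.0348 to 0.454 (median 0.290). The other tag pairs held at most 4 class II UMIs in any thinned cell, too few to read their r. The p53 and cell death list had r of 0.324 pooled, at the 97.6 percentile of random lists, and 0.171 within tag pairs, at the 90.3 percentile. Of its 16 members tested, 5 reached r of 0.3 pooled and 2 within tag pairs. Mlkl, which carries out necroptosis, had 0.440 pooled and 0.302 within, and Casp8, an initiator caspase, 0.364 and 0.265, while Bax, which permeabilises mitochondria, stood at -0.0577 pooled.

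Proliferation and hypoxia lists had negative r with the interferon-gamma score, small over all cells. The S phase list had r of -0.107 pooled, at the 11.7 percentile, and -0.169 within tag pairs, at the 0.57 percentile, and was negative in 11 of 15. The G2/M list had -0.125 and -0.124, and the hypoxia and glycolysis list -0.0894 and -0.210, negative in 14 of 15 tag pairs, each inside the central 95% of random lists. A simulated list without a link within tumors had r of -0.183 there when all linked genes rose. Negative values within tumors can therefore arise without a link. That simulated list was the class I list, with no variation within tumors beyond counting noise and the shift in shares. The simulation therefore cannot decide whether the values of the proliferation and hypoxia lists arose in that way. Without cluster 3, an alternative chosen after seeing the data, r was -0.282 for the S phase list, -0.330 for the G2/M list and -0.153 for the hypoxia and glycolysis list. Cluster 3 stood at 756 CPM for S phase, 1169 CPM for G2/M and 1865 CPM for interferon-gamma genes. Over kept cells these levels were 1803, 4966 and 3654 CPM. Leaving out cells low in both kinds of list lowers r by construction, so these values add no separate support. Within tag pairs, 0 of 35 S phase members, 0 of 50 G2/M members and 2 of 18 hypoxia members tested had positive r, against 5476 of all 10931 genes. Members of a list vary together, so these counts are not independent. The lactate dehydrogenase gene Ldha had the strongest r of the hypoxia list, at -0.236 pooled and -0.295 within. The other 5 lists lay inside the range of random lists, with pooled r of -0.0616 for the melanocytic list, -0.0947 for the neural crest list, 0.0569 for immediate early genes, 0.0833 for the unfolded protein response and 0.0317 for MAPK output. Their strongest members were Slc24a5 (-0.119 pooled, -0.0820 within), Zeb2 (0.215 and 0.256), Jun (0.238 and 0.20), Ddit3 (0.241 and 0.0676) and Etv4 (-0.154 and -0.0970).

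**Figure D4:**
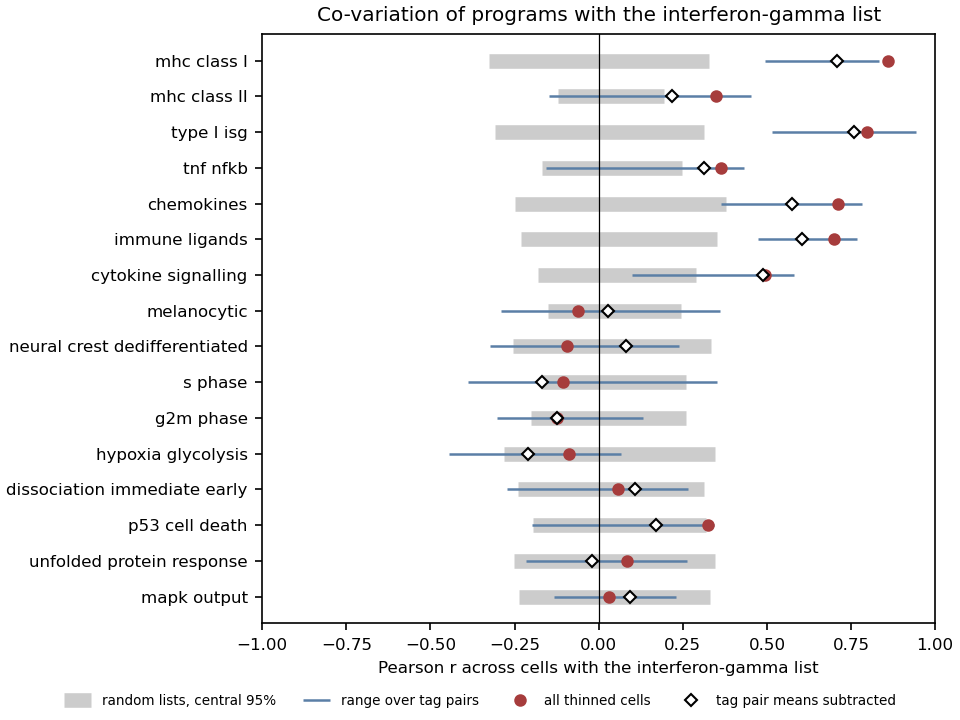
Pearson r across cells of each program list (vertical axis) with the interferon-gamma list (horizontal axis), over all 1233 thinned cells (filled circles) and after each tag pair's mean was subtracted (open diamonds). Blue lines span the 15 tag pairs with at least 20 thinned cells and grey bars the central 95% of 10000 random lists; class I MHC lies at 0.860 and 0.707, outside its bar.

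Gene by gene, outside the interferon-gamma list, the highest r belonged to genes of antigen processing from the class I list. Of 10931 genes detected in at least 5% of kept cells, 246 had r of at least 0.3 with the interferon-gamma score and 42 had r of -0.3 or lower. Outside the list itself and without genes whose symbols start with Rpl, Rps or mt, 226 of 10804 were at or above 0.3 and 13 at or below -0.3, and 162 were at or above 0.3 within tag pairs. The highest was Psmb9 (ENSMUSG00000096727, r 0.818 pooled, 0.607 within), an immunoproteasome subunit encoded on chromosome 17 from 34181987 to 34187764 (GRCm38). Psmb8 (0.810 pooled, 0.610 within, 34197721 to 34201454), another immunoproteasome subunit, lies near it, and Tap1 (0.798 pooled, 0.636 within, 34187553 to 34197225), a peptide transporter, overlaps its annotation on the opposite strand. Psmb10, Psme1 and Psme2 of the proteasome had r of 0.758, 0.740 and 0.704, which were 0.551, 0.473 and 0.467 within tag pairs, and Tapbp and Tap2 of peptide loading 0.726 and 0.690, which were 0.536 and 0.527. The class I heavy chain genes H2-T22, H2-T23, H2-K1 and H2-D1 had r of 0.773, 0.772, 0.707 and 0.699 pooled, and 0.591, 0.548, 0.420 and 0.425 within tag pairs. These heavy chain genes resemble one another, and their single values are uncertain where the authors' counting could divide UMIs among them.

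Outside the class I list, Ifit3, Isg15 and Xaf1 of the type I interferon list were among the 20 highest, with r of 0.733, 0.706 and 0.697 pooled and 0.696, 0.644 and 0.575 within tag pairs. Gm4951 had r of 0.784 pooled and 0.703 within, Phf11d 0.731 and 0.604, Samhd1, which degrades nucleotides, 0.722 and 0.609, and Herc6 0.701 and 0.628. The surface marker Ly6a fell further, from 0.731 to 0.446. All 20 were positive in at least 14 of the 15 tag pairs. By list, 19 of 20 class I genes, 20 of 20 type I genes, 5 of 8 chemokine genes, 3 of 5 immune ligand genes and 2 of 17 TNF and NF-kB genes tested reached r of 0.3 pooled. Within tag pairs these counts were 17, 20, 3, 3 and 1. Vcam1, an adhesion molecule, was the highest of the last list at 0.348 pooled and 0.301 within. Stat2 was the highest of cytokine signalling at 0.530 and 0.422.

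The 10 genes with the lowest r ranged from -0.450 to -0.303 pooled. Ndufa4 (ENSMUSG00000029632), a subunit associated with cytochrome oxidase, had the lowest r (-0.450), which was -0.113 within tag pairs and positive in 5 of 15. The elongation factor genes Eef1b2 and Eef1g had -0.429 and -0.357 pooled and -0.307 and -0.365 within, and the ribosome-associated Rack1 and Naca -0.390 and -0.375 pooled and -0.351 and -0.324 within. Npm1, a nucleolar protein, had -0.354 pooled and -0.384 within, Ppp1r14b -0.333 and -0.344, Nap1l1 -0.318 and -0.292, Hnrnpa0 -0.333 and -0.197, and Mrpl34 -0.303 and -0.209. Eef1b2, Rack1, Naca, Ppp1r14b and Mrpl34 were positive in 0 of 15 tag pairs. Genes at or below -0.3 numbered 1 without thinning and 100 without cluster 3, rather than 13, so this side depended on the processing. The count without thinning used all 1643 kept cells, with those too shallow to be thinned. The effects of thinning and of the set of cells cannot be told apart there. Within tag pairs, genes at or below -0.3 numbered 11, of which 6 were among the 13.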

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

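These values come from barcodes outside the kept cells, where a list stood at least 2 times above its level in the kept cells. They were chosen after the data were seen, and no explanation was tested for them. In the 437 barcodes with a high mitochondrial share, the melanocytic list stood at 179 CPM against 86.8 CPM in kept cells, with Slc24a5 at 87.3 and Pax3 at 74.3 CPM. The fibroblast list stood there at 1782 CPM against 876 CPM, nearly all from Col3a1 at 1638 CPM. The macrophage list stood at 57.8 CPM against 6.37 CPM, of which a single barcode held 84.7%, and without that barcode the level was 8.92 CPM. In the 199 barcodes with 3 or more hashtags, the macrophage list stood at 102 CPM, and 3.47 CPM without the 4 barcodes that held at least 10 of its UMIs. The class II MHC list stood at 305 CPM against 145 CPM in kept cells, and at 204 CPM without those 4 barcodes. The pericyte and smooth muscle list stood at 6.32 CPM against 1.33 CPM, and at 1.60 CPM without 2 barcodes.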

How the results depend on the processing

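Alternatives named here as added were chosen after seeing the data. Among the values that answer a question of the design, 118 values under an alternative stayed within their limit and 14 moved. No r outside the range of random lists changed sign, while inside it the melanocytic list turned to 0.0182, and the neural crest list to 0.0539, without thinning. With tag pair means subtracted (added), these were 0.0285 and 0.0825, and the unfolded protein response turned to -0.0198, and without cluster 3 (added) the neural crest list was 0.0509. The limit was 1.5 times for counts, the Poisson interval for levels and the SD over tag pairs for r. A UMI minimum of 500 kept 20270 barcodes rather than 1643, by its construction, since it takes in the barcodes of little RNA. Clusters numbered 3 at resolution 0.25 and 11 at resolution 1.0, rather than 5. Without cell cycle, interferon, MHC and chemokine genes they again numbered 5, but with other cells (adjusted Rand index 0.508), and at most 58.5% of cluster 2 and 52.8% of cluster 3 stayed in a shared cluster, and values that rest on these clusters were not recomputed with that clustering. With doublets kept, the interferon-gamma list rose to 3801 CPM. With a linear score, r with the interferon-gamma list was 0.752 for class I MHC and 0.559 for chemokines. With each tag pair's mean subtracted (added), it was 0.707 for class I, 0.576 for chemokines, 0.604 for immune ligands and 0.171 for p53 and cell death genes. Without cluster 3, led by Mgp (added), r was -0.330 for the G2/M list. For the S phase list it was -0.282, which stayed within its limit of 0.208. Genes at or below -0.3 numbered 1 without thinning and 100 without cluster 3, rather than 13. Values without thinning used all 1643 kept cells, so the set of cells changed too. Tag pairs numbered 18 with a minimum of 10 cells (added) and 6 with the planned 100, and the CLR rule gave 6. Outside these counts of values, the CLR rule changed the interferon-gamma level of a tag pair by up to 28.5%. That change was in HTO2/HTO4, from 1672 to 1195 CPM. Among the 6 pairs with at least 100 cells the largest change was in HTO2/HTO8, from 5094 to 4894 CPM. Apart from the UMI minimum, the cause was not tested. For single lists and genes, 138 values stayed and 30 moved. Leaving out clusters led by fixed markers of other cell types gave no value, as no cluster had such a marker among its top 10 genes. The alternatives with DESeq2 and without a count filter were not run, since the comparisons between conditions were not made. No paired analysis was possible because the tags carry no condition or replicate number. Depth limits genes of low level, as 62.0% of simulated linked genes with a log2 change of 1 per SD were found, against 100% of those of at least 50 CPM.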

Other observations

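Of the tests below, those on depth and free RNA for the interferon-gamma ranges, on filters, on CFP-positive cells and on macrophages were chosen after the result was seen, and those on abundant genes, tag cutoffs and free RNA for class II before it.

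Transcripts of class II MHC genes were concentrated in a minority of cells. Of 1233 thinned cells, 911 (73.9%) held no UMI of the class II list and 103 (8.35%, exact interval 6.87 to 10.0%) held 10 or more, and the 10% of cells with the most held 92.4% of its UMIs. The 103 cells lay in 6 tag pairs, with 12.8% of the thinned cells of HTO8/HTO10, 14.7% of HTO1/HTO9, 15.3% of HTO2/HTO8, 15.4% of HTO3/HTO9, 15.7% of HTO7/HTO10 and 17.4% of HTO6/HTO7. In each of the other 12 tag pairs the count was 0, and the highest number of class II UMIs in a thinned cell there was 4. Cd274, which encodes the checkpoint ligand PD-L1 and was chosen after its value was seen, had r of 0.514 with the interferon-gamma score, and 0.434 within tag pairs.

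Pairs of lists other than the interferon-gamma list were also correlated across cells. Within tag pairs, the TNF and NF-kB list had r of 0.506 with chemokines, above its 0.312 with the interferon-gamma list and 0.166 with the type I list. The neural crest list had r of -0.371 with the S phase list and 0.310 with cytokine signalling genes. The class I list had -0.356 with S phase genes within tag pairs and -0.212 pooled. Chemokines, cytokine signalling and class I genes were themselves correlated with the interferon-gamma score, which was not removed here. No p-value was computed, as cells are not replicates.

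The levels of the interferon-gamma list fell in 2 separate ranges over the 18 tag pairs. They were 6346 CPM in HTO3/HTO9, 5793 in HTO7/HTO10, 5723 in HTO1/HTO9, 5535 in HTO8/HTO10, 5094 in HTO2/HTO8 and 4615 in HTO6/HTO7. The others were 2149 CPM in HTO4/HTO8, 2074 in HTO5/HTO7, 1700 in HTO1/HTO2, 1699 in HTO4/HTO9, 1672 in HTO2/HTO4, 1561 in HTO2/HTO5, 1502 in HTO3/HTO7, 1449 in HTO3/HTO6, 1410 in HTO6/HTO10, 1394 in HTO6/HTO9, 1195 in HTO3/HTO5 and 912 in HTO1/HTO3. The gap was a ratio of 2.15, against at most 1.31 between other neighbours. The make-up by cluster differed along with these levels. In the order above, cluster 2 held 50, 50.4, 56.7, 47.7, 53.1 and 37.4% of the cells, then 0, 8.33, 8, 6.12, 21.1, 11.5, 15, 0, 1.28, 3.37, 2.33 and 10%. Cluster 3, led by Mgp and Prg4, held 5.22, 5.84, 6.73, 11.9, 3.35 and 15%, then 73.9, 41.7, 34, 51.0, 47.4, 26.9, 40, 44.8, 57.7, 47.2, 50 and 55%. No group was formed from these ranges, and no correlation across tumors was computed.

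After thinning to equal depth the ratio across the gap was 2.38. The levels are shares of UMIs, which thinning leaves unchanged on average in each cell. This ratio therefore cannot decide whether unequal depth played a part. Free RNA cannot lift cells that do not express the list above its own level of 3741 CPM, and the lowest of the upper range was 4615 CPM. Without the 5 most abundant members, which include Iigp1, the ratio was 2.18. The level of free RNA also lay above the highest of the lower range, 2149 CPM. Mixing with free RNA of that level would draw both ranges toward it and narrow the gap. These values argue against free RNA as a cause of the gap, and against a few abundant genes as the whole cause. The condition of each tumor stays open as an explanation and was not tested, since no label ties tags to conditions.

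The 6 tag pairs with the most kept cells (104 to 209) had the 6 highest levels of the interferon-gamma list, and the other 12 held 19 to 89 cells. With barcodes of high mitochondrial share counted too, 6 of the 6 pairs with the most barcodes were still those with the highest levels, which argues against the filter. With each kept cell given to its 2 highest tags, whether or not they passed the cutoffs, the overlap was again 6. This argues against the loss of kept cells that the tag cutoffs left unassigned. Barcodes left out as doublets by the same cutoffs were not returned, so the test cannot decide whether their loss played a part. Cell numbers differed by up to 11 times, and an unequal share of CFP-positive cells in the tumors may account for this. Per the labels, equal numbers of cells were combined before the sort, and the sources used here give no such share, so this cannot be told apart from other reasons.

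For class II transcripts, macrophages and free RNA were weighed. Without the 2 kept cells that held at least 10 macrophage UMIs the class II level was 140 CPM rather than 145, so such cells cannot account for most of it. In tag pair HTO5/HTO7, however, 1 such cell, with 203 macrophage UMIs among 8428, held most of it, since the level fell from 31.3 to 2.64 CPM without that cell, consistent with a macrophage that passed the CFP sort. Free RNA at the level of the barcodes under 800 UMIs gives 0.100% of cells with 10 or more class II UMIs by a Poisson draw, against 8.35% observed. A candidate explanation for the rest, as a hypothesis, is expression of class II genes by some tumor cells, for which no condition could be tested.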
